A study of Mus musculus with 4 samples.

How the data were processed

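Gene expression was measured by RNA sequencing in CD8+ T cells sorted as CD3+CD8+ cells from mouse lung, with 1 library for each combination of model (IPF-LC or LC) and antibody (isotype or CD4-depleting). RNA was extracted with a column kit for small samples, reverse-transcribed with a SMART-Seq low-input kit and made into libraries with a NEBNext Ultra II kit, per the labels. The submitters' processing notes name fastp 0.23.4, STAR 2.7.11a, RSEM 1.3.3 and MultiQC 1.25.2 without giving their roles, and the genome build as GRCm39, also called mm39. The annotation release is not stated. Libraries were assigned to groups by the labels alone; the names of the tables use other words for the conditions, which were not used here. For each library the authors provided 1 gene table with 55401 genes, named by Ensembl identifier and symbol, in the layout of RSEM gene results. The deposited expected counts are estimated reads per gene and are not normalised; between 5.49 and 5.89% of them were not whole numbers. The deposited TPM values (transcripts-per-million) sum to between 999999 and 1000001 in each library. The deposited FPKM values are fragments per kilobase scaled to the library's total and were not used here. Per the file headers, the other columns hold the length and effective length of each gene in bases, of which the length was used in 1 check. Because the annotation at hand is for the older mouse build, it was used for gene types only and no coordinates are given. Where rows shared a symbol, all were kept in the gene counts and gene lists, and for a single named gene the one with the higher mean level stood for it.

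Expected counts were rounded to whole numbers. The library totals were 15439173, 16217677, 14946579 and 15767811 in the order isotype IPF-LC, CD4-depleted IPF-LC, isotype LC and CD4-depleted LC, and the TMM factors of edgeR were 1.01, 0.961, 1.03 and 0.994. Mitochondrially encoded genes took 1.74, 1.82, 1.50 and 1.39% of the counts and the 10 most abundant genes 4.64, 5.01, 4.33 and 4.64%. Log2 ratios of TMM-scaled CPM (counts-per-million) were formed with a prior count of 0.5 for CD4 depletion in each model, for IPF-LC over LC with each antibody, and for the difference between the depletion ratios. Each gene's ratio has an exact conditional binomial 95% interval, which covers counting error only. Counts of genes at least 2-fold apart used the 8433 genes with a mean of at least 10 CPM. A fold against a library with 0 counts is given as at least the fold over a floor of 3 counts per library. This floor is a convention, and the 95% counting interval can reach to a smaller fold. No p-value is given for a comparison between a pair of libraries, since none has a replicate.

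The gene lists, the named genes, the comparisons and the alternatives were fixed before the data were examined, save for 1 alternative named as added later and the tests of technical explanations. There were 37 lists, of T cell states, receptors and responses, metabolism and stress, RNA quality, and markers of T cell subsets and other cell types that a lung sort could hold. A list's median ratio over members with a mean of at least 1 CPM was ranked among 10000 random lists of the same size, drawn from 12231 genes and matched on mean expression in 20 bins. A list stands apart under percentile 2.5 or over 97.5, where 5% of lists of randomly drawn genes lie. Members of a fixed list can vary together, so more of the fixed lists may lie there without an effect. The list of sex-linked transcripts had too few measured members and was not summarised, which leaves 36. The named genes are the 10 highest and 10 lowest of each depletion comparison, by the counting bound nearest 0, among genes with a mean of at least 10 CPM, and the 10 and 10 with the largest ratios in the same direction in both models. To these come the 5 and 5 of each model comparison and of the difference, the 10 with the smallest p in the joint model, up to 4 members of each list with the largest ratios, and a set named in advance that includes Cd8a, Cd8b1, Cd4, Foxp3, Gzmb, Gzma, Prf1, Ifng, Pdcd1, Havcr2, Tcf7, Il7r, Mki67, Itgae, Cxcr6 and Klrg1. Receptor and immunoglobulin segments and gene models without a proper symbol were passed over, and some named genes were left out for length.

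The only test across libraries was an additive edgeR quasi-likelihood model with terms for model and treatment. It was run on the 13050 genes that passed filterByExpr, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. Its 1 residual degree of freedom is the interaction of model and treatment, so a real interaction inflates the error, and the common dispersion was 0.228. DESeq2 and limma-voom were run in the same design as alternatives. On simulated data with 100 genes at each fold among 8433, edgeR recovered 100% of 2-fold and 100% of 4-fold genes with counting noise only, 16% and 95% at a dispersion of 0.05, and 0% and 7% at 0.2. False calls numbered 9, 0 and 1. At a dispersion of 0.05, 309 of 8233 unchanged genes passed the 2-fold mark between a pair of libraries, and at 0.2 it was 2401. List medians were tested on simulated data too: of 400 lists of 20 genes shifted by a log2 ratio of 0.5, 400 stood apart with counting noise only and 392 at a dispersion of 0.05, against 19 and 22 of 400 lists without a shift. The simulated genes varied independently and no higher dispersion was tried, so the rate for genes that vary together was not measured.

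Alternatives were DESeq2 size factors, scaling by total count, the same without receptor segments and mitochondrially encoded genes, minimum means of 1 and 50 CPM, the deposited TPM with a pseudocount of 1 or 0.1 on genes with a mean TPM of at least 10, a prior count of 5, and the whole counting interval beyond 2-fold. For edgeR they were RLE size factors, no filter, a minimum mean of 10 CPM, the tested effect as the only term, and the same with each library left out in turn, which leaves 3 libraries and 1 residual degree of freedom. No scaling moved the median ratio of the 8433 genes by as much as 0.1. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1.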

Results

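RNA sequencing was carried out on CD8+ T cells, sorted as CD3+CD8+ cells from the lungs of C57BL/6J mice. Mice of 2 models, which the labels name IPF-LC and LC without spelling either out, received an isotype control antibody or an antibody that depletes CD4+ cells. This made 4 groups with 1 library each, so no value had a replicate error and no comparison between a pair of libraries could be checked against the spread between animals. The number of mice behind each library is not stated. Total expected counts were 15439173 in the isotype IPF-LC library, 16217677 in the CD4-depleted IPF-LC library, 14946579 in the isotype LC library and 15767811 in the CD4-depleted LC library. Between 14657 and 16415 genes per library had a count. Levels are given as CPM (counts-per-million) after TMM scaling, and ratios as log2 of the first-named over the second-named library. The 95% intervals cover counting error only: the reads carried no molecular identifiers, so they are not independent molecules, and differences between mice are not covered. A fixed gene list is said to stand apart where its median ratio lay outside the central 95% of 10000 random lists of like size and expression, which describes these libraries and is not a test.

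The sorted cells carried the transcripts of CD8 T cells in each library. Cd8a and Cd8b1, which encode the chains of the CD8 coreceptor, were measured at 518 and 972 CPM in the isotype IPF-LC library, 353 and 654 in the CD4-depleted IPF-LC library, 476 and 693 in the isotype LC library, and 452 and 828 in the CD4-depleted LC library. None of the 18 measured CD8 T cell identity genes differed 2-fold between the depleted and isotype library of either model. Cd8a and Cd8b1 were nonetheless lower after depletion in IPF-LC, at -0.55 (-0.60 to -0.50) and -0.57 (-0.61 to -0.54), against -0.07 and 0.26 in LC. Cd4, the coreceptor that the depleting antibody recognises, was low throughout, with 73, 0, 12 and 16 counts in the same order. Its level was thus at least 24.3-fold lower after depletion in IPF-LC by the floor of 3 counts per library. The counting interval reached to a log2 ratio of -4.27, a smaller fold. In LC the log2 ratio was 0.38 (-0.78 to 1.61) and no difference was detectable at this depth. Transcripts of other cell types were present as well, and differed between libraries. The 20 macrophage and monocyte markers summed to 3869 CPM in the isotype IPF-LC library, 1281 in the CD4-depleted IPF-LC library, 5212 in the isotype LC library and 222 in the CD4-depleted LC library.

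The first question was how CD8+ T cells of IPF-LC mice differed when CD4+ cells had been depleted. Inhibitory receptor genes and regulatory T cell markers were higher in the depleted library, while cytotoxic effector genes went both ways. Pdcd1, which encodes the inhibitory receptor PD-1, stood at 122 CPM after depletion and 33.2 with isotype antibody, a log2 ratio of 1.88 (95% counting interval 1.74 to 2.03). Ctla4, another inhibitory receptor, was 5.56-fold higher (2.47, 2.35 to 2.60). Foxp3, the transcription factor that defines regulatory T cells, was 19.5-fold higher, at 29.3 against 1.47 CPM (4.28, 3.71 to 4.99). Gzmb, a granzyme of cytotoxic granules, was 2.01-fold higher (1.01, 0.92 to 1.10), while Ifng (-0.09, -0.29 to 0.11) showed no difference detectable at this depth and Prf1, the pore-forming perforin, had a ratio of -0.30 (-0.41 to -0.19).

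Of the 19 measured inhibitory receptor and exhaustion genes, 8 were at least 2-fold higher in the depleted IPF-LC library and 0 were 2-fold lower, with a median log2 ratio of 0.65 at percentile 100 of the random lists. Besides Pdcd1 and Ctla4, the members included Tnfrsf9, the costimulatory receptor 4-1BB, at 1.85, and Entpd1, the ectonucleotidase CD39, at 1.57. Havcr2, which encodes TIM-3, had a ratio of -0.20 (-0.52 to 0.11). Among the 13 regulatory T cell markers, 9 were at least 2-fold higher and 0 were lower by that much (median 1.61, percentile 100): beside Foxp3, Tnfrsf4 had a ratio of 3.63, Ikzf4 2.32 and Ikzf2 1.61. The lists overlap: Ctla4 is also a regulatory T cell marker, and 8 of the 14 listed regulatory T cell markers are also in another list. Terminal effector genes had a median of 0.56 (percentile 99.98), with 4 of 15 at least 2-fold higher, among them Klrg1 at 2.26 (1.91 to 2.65) and the transcription factor gene Bhlhe40 at 1.97. Of the cytotoxic effector genes, 4 of 17 were at least 2-fold higher, including Gzmk (2.59) and Fasl (1.41), and 3 were lower by that much, including Tnf (-1.60). Their median was -0.04 and their mean 0.0002, opposite in sign and both close to 0.

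Genes tied to life in tissue and to TGF-beta were also higher in the depleted IPF-LC library. TGF-beta signalling genes and targets had a median of 0.75 (percentile 100), with 7 of 21 at least 2-fold higher and 1 lower. Smad7, a feedback inhibitor of the pathway, was among the higher ones at 1.54 (1.42 to 1.66). Furin, a protease that matures TGF-beta, had a ratio of 1.82 but belongs to the list of fibrosis-linked products, whose median was -0.12. Tissue residency genes had a median of 0.61 (percentile 99.98): Ccr8 (2.80), Rgs1 (1.87) and Cxcr6 (1.13) were higher, whereas Itga1 had a ratio of -1.42 and Itgae, which encodes the CD103 integrin chain, one of -0.31. Chemokine receptor and homing genes had a median of 0.53 (percentile 99.97), with 6 of 21 at least 2-fold higher, among them Ccr4 at 2.05, Ccr2 at 1.96 and Cxcr3 at 1.49. Costimulatory receptors had a median of 0.48 (percentile 99.7). Among cytokine receptors, Il1r2 (2.61), Il12rb2 (2.5) and Il10ra (1.78) were higher, and the list median of 0.23 stayed within the range of random lists (percentile 95.3).

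Naive and central memory genes had a median of -0.13 in this comparison (percentile 3.12, within the range of random lists). Tcf7, a transcription factor of naive and memory T cells, had a ratio of -0.36 (-0.40 to -0.31). Proliferation genes were higher, with 12 of 57 at least 2-fold higher, 0 lower by that much and a median of 0.51 (percentile 100). Pclaf and Ccna2, which encode proteins of the dividing cell, had ratios of 1.53 and 1.42, and Mki67 one of 0.73 (0.51 to 0.94). Type I interferon response genes were lower, with a median of -0.58 (percentile 0), 8 of 41 at least 2-fold lower and 1 at least 2-fold higher. Slfn5 (-2.32), Cmpk2 (-1.75) and Usp18 (-1.37) were among the lower ones.

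Markers of cells outside the CD8 gate were lower in the depleted IPF-LC library at the same time. The macrophage and monocyte markers had a median of -1.56, with 18 of 20 at least 2-fold lower, the endothelial markers one of -2.44 with 11 of 12, the fibroblast markers -2.05 with 11 of 12, and the lung epithelial markers -2.14 with 7 of 10. Neutrophil markers had a median of -2.35, or -2.17 with undetected members at the floor, and B cell and plasma cell markers one of -1.14. Csf1r, the macrophage growth factor receptor, had a ratio of -3.13 (-3.51 to -2.78), and the endothelial receptor gene Kdr, not detected after depletion, was at least 131-fold lower. C3 and Dcn, which encode a complement component and a matrix proteoglycan, were at least 47.9-fold and 56.5-fold lower. In all, 344 of the 8433 genes with a mean of at least 10 CPM were at least 2-fold higher in the depleted IPF-LC library and 508 were at least 2-fold lower. In the simulation, 309 of 8233 unchanged genes passed the 2-fold mark at a dispersion of 0.05 and 2401 at 0.2. The additive model's common dispersion was 0.228, which a real interaction of model and treatment would inflate, so the dispersion that applies here is not known. Such counts, here and in the other comparisons, may arise in part or in whole without an effect, and the share is not known. Genes with the highest ratios by the counting bound nearest 0 included Entpd4b (4.2), Ifitm1 (4.15) and Brca1 (3.23). With only the genes whose whole counting interval lay beyond 2-fold, the counts were 207 and 325. With a mean of at least 50 CPM they were 118 higher and 66 lower, so that more genes were higher than lower.

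The same question was asked of LC mice. Cytotoxic effector and inhibitory receptor genes, Ctla4 excepted, were for the most part lower in the depleted LC library: Gzmb had a ratio of -0.82 (-0.89 to -0.75), Prf1 -1.29 (-1.39 to -1.18), Ifng -1.29 (-1.52 to -1.06), Pdcd1 -0.66 (-0.76 to -0.56) and Havcr2 -1.66 (-1.84 to -1.48). Foxp3 was 8.32-fold higher after depletion, at 32.5 against 3.88 CPM (3.06, 2.68 to 3.48), and Ctla4 was 2.12-fold higher (1.09, 1.00 to 1.18). Itgae was 2.28-fold higher (1.19, 1.10 to 1.28). Mki67, a marker of dividing cells, stood at 92.9 CPM after depletion and 33.7 with isotype antibody (1.46, 1.32 to 1.61).

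Cytotoxic effector genes had a median of -0.84 in this comparison (percentile 0), with 7 of 17 at least 2-fold lower and 0 higher by that much. The chemokine genes Ccl3 (-3.93) and Ccl4 (-2.19) were among these. For inhibitory receptor and exhaustion genes the median was -0.66 (percentile 0), with 6 of 19 at least 2-fold lower, including Entpd1 (-2.23) and Tnfrsf9 (-1.26), and 1 at least 2-fold higher, Ctla4. For terminal effector genes it was -0.74 (percentile 0), with Zeb2 at -3.53 and Klrk1 at -1.48. Tissue residency genes had a median of -0.22 (percentile 0.97) and a mean of -0.77, with Itga1 at -4.16 and Ccr8 at -1.17. With the stricter minimum of 50 CPM, that median was 0.13, so its sign depended on weakly expressed members. Natural killer cell markers had a median of -2.14, with 9 of 12 at least 2-fold lower, Klre1 (-2.56) among them. The lower values of these groups came together with those of macrophage and monocyte markers, all 20 of which were at least 2-fold lower in the depleted LC library.

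Proliferation genes in LC had a median of 0.78 (percentile 100), with 20 of 57 at least 2-fold higher and 0 lower by that much, such as Ccna2 (1.64), Pclaf (1.42) and Foxm1 (1.91). Regulatory T cell markers had a median of 0.41 (percentile 99.4), with 3 of 13 at least 2-fold higher and 1 at least 2-fold lower. CD4 T helper markers, a list without Foxp3, had a median of 0.81 (percentile 99.96), with Maf at 0.99, against 0.68 (percentile 99.1) and a Maf ratio of 2.61 in IPF-LC. There the mean of this list was 0.11, with 4 of 10 members at least 2-fold higher and 2 lower by that much, Cd4 among the latter. Ccr4, a chemokine receptor of type 2 helper and regulatory cells, stood at 96.3 CPM after depletion and 3.75 with isotype antibody (4.67, 4.30 to 5.09). The naive and central memory list had a median of 0.29 (percentile 98.8) but a mean of -0.01, since Ly6c1, with 548 counts against 3, lay far below the rest (-7.31, -9.82 to -5.98). Satb1 (1.11) and Klf2 (0.98), transcription factors of quiescent T cells, were higher. Costimulatory receptors had a median of 0.30 (percentile 97.6), chemokine receptor and homing genes 0.11 (percentile 61.4), TGF-beta genes 0.14 (percentile 78.3) and cytokine receptors 0.03 (percentile 27.9), the last of which turned to -0.03 under another scaling and had a mean of -0.26.

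Type I interferon response genes were lower in the depleted LC library as well, with 21 of 41 at least 2-fold lower, 1 at least 2-fold higher and a median of -1.02 (percentile 0). Rsad2, an antiviral enzyme, had a ratio of -2.28 (-2.61 to -1.97), and Ifit1 and Ifit3 had ratios of -1.95 and -1.88. Macrophage and monocyte markers had a median of -6.67, or -5.93 with undetected members at the floor. The lectin receptor gene Clec7a and the kinase gene Syk, both expressed by myeloid cells, were not detected after depletion and were at least 606-fold and 461-fold lower. Medians were -4.13 for endothelial markers (-3.98 at the floor), -4.48 for fibroblast markers (-4.01), -6.72 for neutrophil markers (-5.43), -3.26 for lung epithelial markers and -1.65 for B cell and plasma cell markers. Across all 8433 genes, 218 were at least 2-fold higher in the depleted LC library and 493 were at least 2-fold lower. When 232 genes whose levels followed the macrophage list across the 4 libraries were left out, an alternative chosen after the data were seen, 271 of the lower genes were left. The filter uses the same 4 libraries in which that list was lower, so it takes out lower genes by construction. With only the genes whose whole counting interval lay beyond 2-fold, 133 were higher and 407 lower. With a mean of at least 50 CPM, 67 were higher and 70 lower, without the excess of lower genes.

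**Figure D1:**
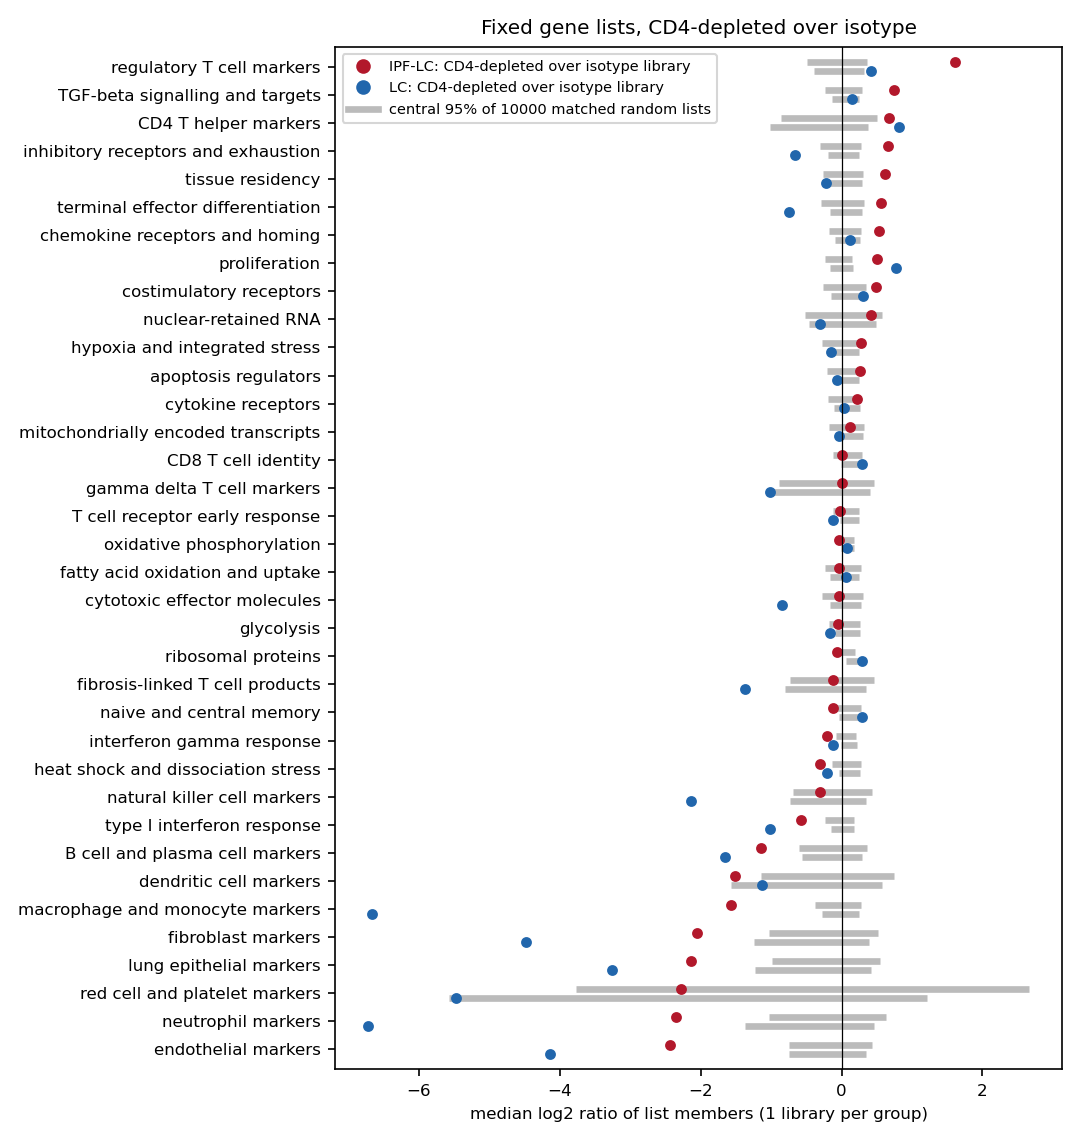
Median log2 ratio of each fixed gene list, CD4-depleted over isotype library, in IPF-LC and in LC, with 1 library per group. The inhibitory receptor list lies at 0.65 in IPF-LC and -0.66 in LC, whereas the macrophage list lies at -1.56 and -6.67 (-5.93 with undetected members at the floor).

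The depletion comparisons of IPF-LC and LC share no library, so genes that went the same way in both can be set side by side. Foxp3, Ctla4, Smad7 and Furin were at least 2-fold higher after depletion in both models, with Smad7 at 1.54 and 1.09 and Furin at 1.82 and 1.23 in IPF-LC and LC. Il17f, a cytokine of type 17 T cells, stood at 23.7 CPM after depletion against 2.5 in IPF-LC (3.23, 2.77 to 3.76) and at 24.3 against 0.906 in LC (4.70, 3.98 to 5.63). Hey1, a target of Notch, and Lrig1, a regulator of growth factor receptors, had ratios of 2.11 and 2.03 in IPF-LC and 2.40 and 2.11 in LC. On the lower side stood genes of other cell types, such as Tspan7 (-4.79 in IPF-LC; 1.66 against 65.0 CPM in LC), Plvap (-3.23 and -4.26), Fn1 (-1.96 and -4.84) and Il1b (-2.23 and -4.54).

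In total 51 genes were at least 2-fold higher in both models, where independent lists of those sizes would share 8.9, and 234 were at least 2-fold lower in both, where independent lists would share 29.7. Opposite directions were found for 24 genes higher in IPF-LC and lower in LC and for 7 genes lower in IPF-LC and higher in LC, where independent lists would share 20.1 and 13.1. Across the 8433 genes, which are not independent replicates, the depletion ratios of the models had a Pearson correlation of 0.469 and a Spearman correlation of 0.237. Without the 234 genes lower in both models, these were 0.138 and 0.172, a fall partly built into leaving out genes picked for low ratios in both. A joint edgeR model of all 4 libraries, with model and treatment as additive terms and 1 residual degree of freedom, called 0 of 13050 genes higher or lower with depletion at an adjusted p under 0.05. Its unadjusted p lay under 0.05 for 409 higher and 896 lower genes, and the smallest adjusted p was 0.204, shared by C3 and Tspan7. Foxp3 had a log2 change of 3.64 (SE 0.533, adjusted p = 0.218). DESeq2 called 95 genes higher and 375 lower in the same design, limma-voom called 0 in either direction, and edgeR on genes with a mean of at least 10 CPM called 39 and 95. With depletion as the only term, edgeR called 0 genes in all 4 libraries, 16 lower without the CD4-depleted IPF-LC library and 1 lower without the isotype IPF-LC library.

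**Figure D2:**
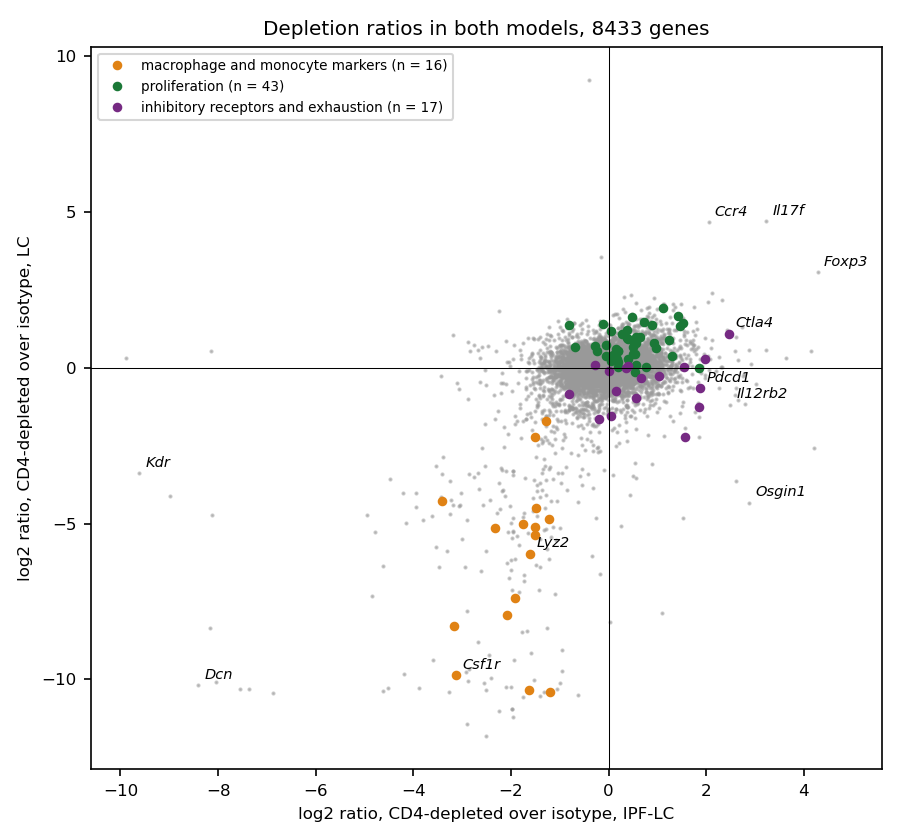
Log2 ratio of each of 8433 genes, CD4-depleted over isotype library, in IPF-LC on the horizontal axis and in LC on the vertical axis, with 1 library per group. The 234 genes at least 2-fold lower in both models fill the lower left, and the ratios of genes with a count of 0 in a library depend on the prior count of 0.5.

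With isotype antibody, CD8+ T cells of IPF-LC mice were compared with those of LC mice, to ask how the models differed without depletion. Inhibitory receptor genes and regulatory T cell markers were lower in the IPF-LC library. Pdcd1 stood at 33.2 CPM in IPF-LC and 136 in LC (-2.03, -2.17 to -1.89), Tnfrsf9 had a ratio of -2.81 (-3.02 to -2.61), Havcr2 -2.57 and Gzmb -1.54. Spp1, which encodes osteopontin, was the other way, at 1273 CPM in IPF-LC and 158 in LC (3.01, 2.95 to 3.07). Since Spp1 was also lower after depletion in both models, as macrophage markers were, its cell of origin is not resolved here. Inhibitory receptor and exhaustion genes had a median of -1.03 (percentile 0), with 10 of 19 at least 2-fold lower and 0 higher by that much. Regulatory T cell markers had a median of -1.08 (percentile 0), with Il2ra at -2.46 and Tnfrsf4 at -3.54, and 1 member was at least 2-fold higher. Terminal effector genes had a median of -0.75, tissue residency genes -0.66 and cytotoxic effector genes -0.32, each below the central 95% of random lists. Proliferation genes were lower in IPF-LC, with 15 of 57 at least 2-fold lower (median -0.52), Ccnb1 (-1.96) among them. Naive and central memory genes had a median of 0.38 (percentile 100), with Tcf7 at 0.43. Type I interferon response genes had a median of -0.20 and TGF-beta genes -0.16 (percentile 3.30). Macrophage and monocyte markers had a median of -1.16 with 12 of 20 at least 2-fold lower, neutrophil markers one of -3.80, endothelial markers -0.45, fibroblast markers -0.48, lung epithelial markers -1.14, and B cell and plasma cell markers 0.06 with a mean of -0.59. Natural killer cell markers had a median of -0.60 (percentile 1.89), CD8 T cell identity genes 0.26 (percentile 99.5), ribosomal protein genes 0.28 (percentile 100, 49 of 49 above 0), mitochondrially encoded transcripts 0.20 (percentile 92.6) and nuclear-retained RNA -0.23 (percentile 12.8). F13a1, a coagulation factor gene expressed by monocytes and macrophages, had a ratio of -5.10. Among the 8433 genes, 161 were at least 2-fold higher in IPF-LC and 346 were at least 2-fold lower. With the whole counting interval beyond 2-fold, 59 were higher and 237 lower, and with a mean of at least 50 CPM the counts were 27 and 48.

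After CD4 depletion, genes of inhibitory receptors, effector cells and tissue residency lay higher in IPF-LC than in LC. Inhibitory receptor and exhaustion genes had a median of 0.49 in the depleted IPF-LC over the depleted LC library (percentile 99.99), with 1 of 19 at least 2-fold higher and 1 at least 2-fold lower, Pdcd1 at 0.52 (0.41 to 0.62) and Havcr2 at -1.11. The medians were 0.29 for cytotoxic effector genes, 0.29 for terminal effector genes and 0.51 for tissue residency genes, each above the central 95% of random lists. Ccl4 (2.56), Klrg1 (1.70), Ccr8 (1.56) and Il10ra (1.70) were higher in IPF-LC. Foxp3 showed no difference detectable at this depth (-0.15, -0.34 to 0.03), and regulatory T cell markers had a median of 0.15 (percentile 81.1). Proliferation genes were lower in IPF-LC, with a median of -0.89, 27 of 57 at least 2-fold lower and Mki67 at -1.59 (-1.74 to -1.44). CD8 T cell identity genes had a median of -0.14 and naive and central memory genes one of -0.02. Type I interferon response genes had a median of 0.21 (percentile 99.1), with Rsad2 at 1.51. These values came beside higher macrophage and monocyte markers in IPF-LC, with a median of 2.85 (2.73 at the floor) and 15 of 20 at least 2-fold higher, and natural killer cell markers at 1.27. The RNA quality lists differed too: mitochondrially encoded transcripts had a median of 0.50 (percentile 100), with 15 of 15 above 0, and nuclear-retained RNA one of 0.70 (percentile 99.6), with 2 of 4 at least 2-fold higher. Spp1 stood at 640.4 CPM in IPF-LC and 4.40 in LC (7.17, 6.84 to 7.55), and Mmp12, a macrophage elastase, was at least 129-fold higher. Among the 8433 genes, 278 were at least 2-fold higher in IPF-LC and 217 were at least 2-fold lower, against 262 and 252 with scaling by total count and 32 and 11 with a mean of at least 50 CPM. Without the genes that followed the macrophage list, 145 were higher. With the whole counting interval beyond 2-fold, the counts were 176 and 102.

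The model comparisons, with isotype antibody and with depletion, share no library either. Only 5 genes were at least 2-fold higher in IPF-LC in both, where independent lists would share 5.3, and 32 were lower in both, where independent lists would share 8.9. Ccnb1, a mitotic cyclin, was lower in both (-1.96 and -1.85), as were Il2ra (-2.46 and -1.45), Ccna2 (-1.12 and -1.35) and Havcr2 (-2.57 and -1.11), while Spp1 was higher in both. For 91 genes the direction was lower in IPF-LC with isotype antibody and higher with depletion, against 11.4 for independent lists, and for 16 it was the reverse, against 4.1. Leaving out the genes that followed the macrophage list took those lower with isotype antibody from 346 to 287 and those higher with depletion from 278 to 145. The 91 genes were not counted again without them. Pearson and Spearman correlations across genes were -0.155 and -0.130, and the former was -0.0882 without the genes that followed the macrophage list. The joint edgeR model called 0 genes higher or lower in IPF-LC over LC, with an unadjusted p under 0.05 for 93 higher and 173 lower genes. DESeq2 called 0 higher and 5 lower, and limma-voom 0.

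The design asks last whether depletion acted differently in the models, which 1 library per group leaves untestable: the difference between the depletion ratios, IPF-LC minus LC, is a value without a test. It was 1.46 for the median of inhibitory receptor and exhaustion genes, 1.07 for terminal effector genes, 1.04 for tissue residency genes, 1.01 for regulatory T cell markers and 0.98 for cytotoxic effector genes. It was negative for CD4 T helper markers at -1.04 (percentile 0.4, 5 of 10 at least 2-fold lower), ribosomal protein genes at -0.35 (percentile 0), CD8 T cell identity genes at -0.34 (percentile 0.46), proliferation genes at -0.33 and naive and central memory genes at -0.39. Pdcd1 had a difference of 2.54, from 33.2 to 122 CPM in IPF-LC and from 136 to 85.6 in LC, so that its lowest level was in the isotype IPF-LC library. Gzmb showed the same order, with 97.3, 196, 283 and 160.2 CPM in the isotype and depleted IPF-LC and the isotype and depleted LC libraries. Lists outside the T cell programs differed as well: the value was 4.10 for macrophage and monocyte markers, 4.47 for neutrophil markers (3.92 with undetected members at the floor), 1.93 for natural killer cell markers and 0.90 for nuclear-retained RNA. Mmp19 and Il1a, genes expressed by macrophages, were at least 242-fold and 213-fold lower after depletion in LC.

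**Figure D3:**
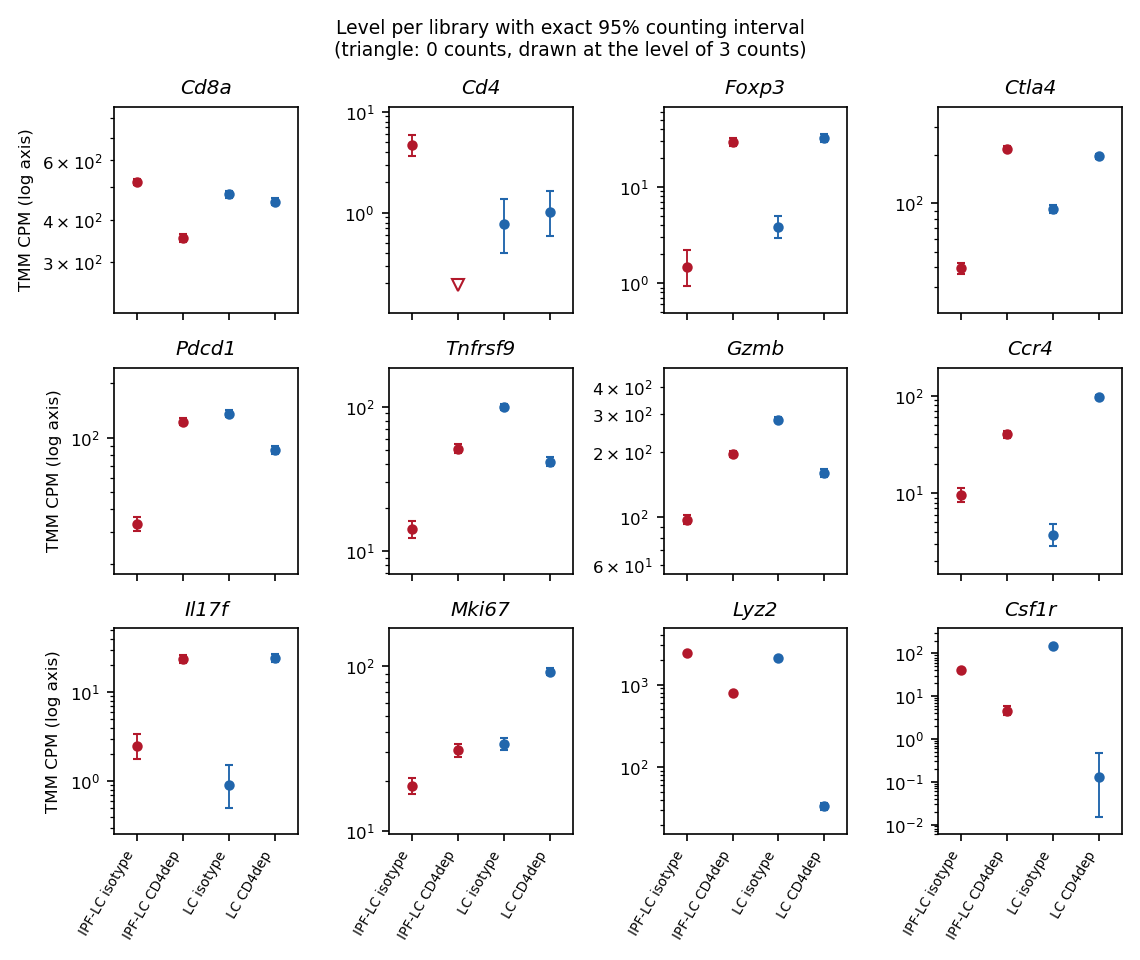
Level of selected genes in each of the 4 libraries, in CPM on a log axis, with exact 95% counting intervals and a triangle at 3 counts where none was found (CD4dep, CD4-depleted). Foxp3 stands at 29.3 and 32.5 CPM in the depleted libraries and at 1.47 and 3.88 in the isotype libraries.

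T cell receptor beta variable segments were spread over many segments in each library, and no single segment dominated. The most used segment was Trbv12-2 with 12.0% of 3449 counts (exact Clopper-Pearson 95% interval 10.9 to 13.1) in the isotype IPF-LC library and Trbv19 with 13.4% of 3349 (12.2 to 14.6) in the depleted IPF-LC library. In LC it was Trbv16, with 12.3% of 2686 (11.03 to 13.55) with isotype antibody and 13.1% of 3595 (12.0 to 14.3) after depletion. The effective number of segments, as the inverse Simpson index, was 14.1, 13.3, 13.6 and 13.1 in the same order. Segment counts do not resolve clones, and no test was made.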

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

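Each test of a technical explanation given here was chosen only after the results were seen, whereas the rule that picked out opposite depletion ratios was set earlier. That rule takes a list whose median ratios in IPF-LC and LC have opposite signs and are each at least 0.5 in size, or a named gene with opposite ratios of at least 1. It took 2 lists and 11 genes, and with 1 library per group the difference was not tested for any of them.

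The terminal effector list had a median of 0.56 in IPF-LC and -0.74 in LC, a median difference of 1.07 between the members' ratios, and the inhibitory receptor list one of 0.65 and -0.66, a median difference of 1.46. Among genes higher after depletion in IPF-LC and lower in LC, the difference was 7.22 for Osgin1 (2.88 and -4.33), 6.79 for Entpd4b, 6.24 for Il1r2, 3.97 for Ccr8, 3.79 for Entpd1, 3.68 for Il12rb2, 3.31 for Ccl4, 3.19 for Il10ra and 3.11 for Tnfrsf9. Lower in IPF-LC and higher in LC were Cdk5rap1 (-3.19 and 1.05), with a difference of -4.25, and Ntrk3 (-2.25 and 1.81), with -4.06. The difference was not tested.

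Markers of cells other than T cells were lower in both depleted libraries, with macrophage medians of -1.56 in IPF-LC and -6.67 in LC (-5.93 with undetected members at the floor). Scaling is argued against, since the lowest median of the CD8 T cell identity list over 4 scalings and both models was -0.066. Cd8a and Cd8b1 themselves had ratios of -0.55 and -0.57 in IPF-LC. More carry-over of other cell types into the isotype libraries may be a cause but was not settled: RNA of 1 kind of cell should differ by about the same ratio, and of 16 macrophage markers with a mean of at least 10 CPM, 13 lay within 1 (log2) of their median in IPF-LC but 8, or 50%, did in LC, where some members had counts at or near 0. The CD3+CD8+ sort should remove such cells, yet Lyz2, the most abundant macrophage marker of the isotype libraries, chosen after its values were seen, stood at 2408 and 2089 CPM in the isotype and 788 and 33.4 in the depleted libraries. Of the 20 macrophage markers 1, Itgax, is also in another list, and a biological effect of depletion on these cells stays open, as untested.

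The inhibitory receptor list was higher after depletion in IPF-LC and lower in LC. The nuclear-retained RNA list, with 4 measured members, had medians of the same signs, 0.42 and -0.30, each within the range of random lists. Its difference between the models was 0.90 (percentile 98.9), above that range. For ribosomal protein genes the difference was -0.35 (percentile 0), and for mitochondrially encoded transcripts it was 0.27 (percentile 97.2), within the range. A difference in RNA quality was not tested as a cause. The choice among 4 scalings did not make the pattern, as the smallest size of either inhibitory list median over them was 0.58. These scalings differ too little to have removed it, so other scaling errors were not tested. Gene length is argued against, with a smallest size of 0.63 after taking off the median of genes of like length. More carry-over of myeloid RNA into the isotype libraries could not raise the list in the depleted IPF-LC library, where its median was 0.65 beside lower macrophage markers. In LC such carry-over into the isotype library cannot be told apart from a difference in T cells: 6 of the 14 members lower in LC would need a level above the one measured in the isotype IPF-LC library, such as 36.1 CPM for Havcr2 against 11.5, but the macrophage profile itself differed between the isotype libraries (SD of member ratios 2.65). More Foxp3-expressing cells within the gate were not tested as a cause of the higher list in the depleted IPF-LC library. Regulatory T cell markers, which share Ctla4 with the inhibitory list, had a median of 1.61 there. In LC their median was 0.41, while the inhibitory list was lower. An effect of depletion on CD8+ T cells that differs between the models may be at work and stays a hypothesis, untested with 1 library per group.

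Foxp3 was higher in both depleted libraries, with 23 and 456 counts in IPF-LC and 60 and 510 in LC. The choice among 4 scalings did not make this rise, as the smallest ratio over them and both models was 3.00. These scalings differ too little to have removed it, so other scaling errors were not tested. Carry-over of cells of the CD4 lineage into the depleted libraries stays open: Cd4 and Zbtb7b together had 101 counts with isotype antibody and 3 after depletion in IPF-LC, a log2 ratio of -5.07 (-7.37 to -3.48), and 36 and 43 in LC, a ratio of 0.24 (-0.44 to 0.92). The antibody itself removes the cells with the most CD4, and the CD4 T helper list had medians of 0.68 and 0.81, so cells with Foxp3 and little Cd4 cannot be told apart from Foxp3 in CD8+ cells. A rise of Foxp3-expressing cells within the CD8 gate may follow depletion, which stays a hypothesis for a replicated experiment.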

How the results depend on the processing

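The alternative that leaves out genes following the macrophage list was chosen only after the results were seen. It is defined by levels in these same 4 libraries, so it takes out by construction genes that change as that list does. No paired analysis was possible because each group had 1 library and the labels give no shared replicate numbers. Of 138 counts and correlations under the alternatives, 101 stayed within the set limits (1.5 times for counts, 0.05 for correlations), and none changed sign. Of the named genes' depletion ratios, 2514 lay within the counting interval and 474 outside it, and no gene with a ratio of at least 2-fold changed sign. Of the list medians, 809 stayed within their counting spread, 356 moved beyond it and 5 that had stood apart changed sign; medians near 0 that did not stand apart also changed sign under some scalings and are not among the 5. Of the 101 list medians that stood apart, 101 still did with DESeq2 size factors, 100 with each total count scaling and 99 with a prior count of 5. With a minimum of 50 CPM it was 59 of 77, and with TPM 81 of 94. A minimum of 1 CPM is the lists' own and a filter leaves a single gene's ratio as it is, so these gave no further values.

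With a mean of at least 1 CPM, more genes were counted: 1081 higher and 1665 lower for depletion in IPF-LC, 715 and 1889 in LC, 651 and 1427 for IPF-LC over LC with isotype antibody, and 1173 and 931 with depletion, with a correlation of depletion ratios of 0.387. With at least 50 CPM, fewer were counted: 118 and 66, 67 and 70, 27 and 48, and 32 and 11 in the same order, with a correlation of 0.364; for depletion in IPF-LC more genes were then higher than lower, the other way around from a mean of at least 10 CPM. The whole counting interval beyond 2-fold, a stricter rule, gave 207 and 325 for depletion in IPF-LC, 133 higher in LC, 59 higher for IPF-LC over LC with isotype antibody, and 176 and 102 with depletion. The correlation of depletion ratios was 0.339 with TPM and a pseudocount of 1 and 0.317 with 0.1; the cause was not tested. Without the 232 genes following the macrophage list, where fewer genes were counted, it was 0.384, the correlation of model ratios was -0.0882, 271 genes were lower for depletion in LC and 145 were higher in IPF-LC over LC with depletion.

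The tissue residency median for depletion in LC was 0.13 with at least 50 CPM, where fewer members were counted. The B cell median for IPF-LC over LC with depletion was -0.22 there, with fewer members too. The hypoxia and integrated stress median for depletion in IPF-LC was -0.044 with at least 50 CPM, -0.10 with TPM and a pseudocount of 1, and -0.10 with 0.1; the cause was not tested.

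For depletion across both models, where edgeR called 0, it called 39 genes higher and 95 lower on genes with a mean of at least 10 CPM, with fewer genes tested. DESeq2 called 95 and 375, and 5 genes lower for IPF-LC over LC; the cause was not tested. The additive model has no residual degrees of freedom with 3 libraries, so each library was left out in turn with the tested effect as the only term, which gave 0 to 16 lower genes with depletion and 0 higher, with 1 without the isotype IPF-LC library and 16 without the depleted IPF-LC library, where the lone library of a group is assumed to vary like the others. With 1 library per group, depth limits only genes of low count: differences between mice, not counting error, stay unmeasured.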

Other observations

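Genes induced by heat shock and by cell dissociation were lower in both depleted libraries. The heat shock and dissociation stress list had a median of -0.30 in IPF-LC (percentile 0.03) and -0.21 in LC (percentile 0.01), with 5 and 3 of 20 members at least 2-fold lower. Hspa1a, an inducible chaperone, stood at 48.8 CPM with isotype antibody and 5.77 after depletion in IPF-LC (-3.07, -3.41 to -2.76), and at 39.7 and 24.9 in LC (-0.67). T cell receptor early response genes had a median of -0.02 in IPF-LC (percentile 22.2) and -0.12 in LC (percentile 0.11): Fos was lower in both (-1.05 and -1.16), while the phosphatase gene Dusp2 was higher (0.93 and 1.69). Interferon gamma response genes had medians of -0.21 and -0.12, both at percentile 0, and Irf8, a myeloid and lymphoid transcription factor, had ratios of -1.13 and -3.58. Apoptosis regulators had medians of 0.27 (percentile 97.2) and -0.06 (percentile 9.46), with Mcl1, a survival factor, at 1.04 and 0.93. Hypoxia and integrated stress genes had medians of 0.27 (percentile 97.9), which changed sign under 3 alternatives, and -0.15 (percentile 4.04). Xbp1, a regulator of the unfolded protein response, had ratios of 1.14 and -0.11.

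Oxidative phosphorylation genes had medians of -0.03 in IPF-LC and 0.07 in LC, with 0 of 63 members at least 2-fold apart in either. Glycolysis genes had medians of -0.06 and -0.17 (percentiles 19.0 and 0.26), with the glucose transporter gene Slc2a1 at 1.10 and 0.02. Fatty acid oxidation and uptake genes had medians of -0.04 and 0.06, with a mean of -0.56 in LC; the uptake receptor gene Cd36 had ratios of -2.00 and -6.48. Ribosomal protein genes had medians of -0.06 and 0.29 (percentiles 0.98 and 99.96). Fibrosis-linked products had medians of -0.12 (percentile 45.5) and -1.38 (percentile 0.32), with Osm, an inflammatory cytokine, at -2.54 and -1.80 and Spp1 at -0.99 and -5.15. Il17a, a cytokine gene, and Ccr6, a chemokine receptor gene, were chosen after their values were seen. Il17a stood at 2.69 and 13.3 CPM in IPF-LC and was at least 48.3-fold higher in LC, and Ccr6 had ratios of 3.41 and 4.54. Gamma delta T cell markers had medians of 0.01, which turned to -0.07 under another scaling and had a mean of -0.68, and -1.01, with Trdc, the delta chain constant gene, at -0.44 and -0.88.

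Other marker and RNA quality lists gave these values for depletion in IPF-LC and in LC. Natural killer cell markers had a median of -0.31 in IPF-LC (percentile 20.6). Dendritic cell markers had medians of -1.51 and -1.12, and red cell and platelet markers -2.28 and -5.47, or -2.28 and -3.26 with undetected members at the floor. Mitochondrially encoded transcripts had medians of 0.12 and -0.04 (percentiles 71.9 and 3.81). The nuclear-retained RNA list, with 4 measured members, had medians of 0.42 and -0.30, with Malat1 at 664 and 1298 CPM in IPF-LC and 833 and 591 in LC. CD8 T cell identity genes had medians of 0.01, which turned to -0.07 under another scaling and had a mean of -0.10, and 0.29 (percentile 97.8). Of the sex-linked transcripts, Xist alone had a mean of at least 1 CPM, at 49.7, 59.0, 49.8 and 48.7 CPM in the order isotype IPF-LC, depleted IPF-LC, isotype LC and depleted LC.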
